A study of Arabidopsis thaliana with 26 samples.

How the data were processed

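RNA sequencing of Arabidopsis thaliana Col-0 plants was analysed. Per the labels, wild-type plants and plants of an msh1 memory line were grown for 10 days on agar medium with 0 or 100 µM 5-azacytidine, an inhibitor of DNA methylation, and whole plants with root were harvested. The memory line descends from plants in which the gene MSH1 had been suppressed. Total RNA went into TruSeq version 2 libraries, a kit that does not mark the strand, and 100-base reads were taken on a HiSeq instrument, per the labels' protocols. The labels describe 26 libraries from 10 biological replicates, each with 2 or 3 technical libraries made from the same RNA.

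The deposited files hold raw read counts per gene and library, as whole numbers, with summary values for reads that lay in no gene, fitted more than 1 gene or aligned to more than 1 place. The submitters' processing notes name the TAIR10 genome and DESeq2, without a version and without saying which step DESeq2 served. The aligner and the counting program are not given in the sources used here. The files hold 33977 gene identifiers and 5 further entries that name no gene and were left out. Of the identifiers, 32548 matched the reference annotation TAIR10.1, which supplied symbols, gene types and positions. Of the 22031 genes tested, 22025 matched and 9025 had a symbol. The genes of the chloroplast and mitochondrial genomes had 0 counts in all libraries, so they were not tested and their lists were left out. The annotation marks no gene as a transposable element gene, so the list of transposon genes was left out as well.

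The counts of the technical libraries were summed per biological replicate, which gave 3 wild-type replicates, 3 treated wild-type replicates, 2 memory-line replicates and 2 treated memory-line replicates. Technical libraries of wild-type replicates 2 and 3 differed most, with a chi-square per degree of freedom of 2.02 and 2.20 over genes with at least 50 counts. In the other biological replicates it was 1.252 to 1.303. The labels do not say whether the replicates were grown separately, so the p-values measure only the spread between these samples. Genes with low counts were removed with filterByExpr of edgeR 4.0.16 by group, with a minimum count of 10 and a minimum total of 15. The counts were scaled with TMM factors. All 4 groups entered a single edgeR quasi-likelihood fit with robust dispersions and no block, in R 4.3.3. The common biological coefficient of variation was 0.166, with 6 residual degrees of freedom and a median of 7.49 prior degrees of freedom. The 5 contrasts were the memory line against wild type without azacytidine, azacytidine against none in each genotype, the difference between both azacytidine responses, and the memory line against wild type on azacytidine. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 fold changes are the size of the change divided by the square root of its F statistic. Levels are CPM, gene counts over library size in units of 1e6 counts, scaled by the TMM factors, and fitted fold changes are on the log2 scale.

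Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01. The p-values were adjusted over 115 tests, 23 lists in 5 contrasts. The lists were clock genes peaking in the morning, clock genes peaking in the evening, flowering time, DNA methylation and silencing machinery, loci silenced by DNA methylation or imprinted, DNA damage response, abscisic acid and drought response, cold regulon, jasmonate biosynthesis and response, salicylate-related immunity, early wound and elicitor response, ethylene response, heat shock response, mitochondrial and oxidative stress response, nuclear-encoded photosynthesis, glucosinolate biosynthesis, flavonoid and anthocyanin biosynthesis, DNA replication, mitosis, root cell type markers, auxin response, iron deficiency response and phosphate starvation response. A list of seed storage and late embryogenesis genes had 3 tested members, under the minimum of 5, and was left out of the list tests. GRXC9, HSP22, HSP23.6 and FIT were dropped because the reference gives these genes other names. Some lists share members: IRT1 and FRO2 stand in those of iron deficiency and root markers, ZAT10 and ZAT12 in those of cold and early wounding, and HSP23.5 in those of heat shock and mitochondrial stress. RD29A of the abscisic acid list and COR78 of the cold list are names of the same gene.

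The lists, contrasts, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names 15 genes in every contrast: MSH1, MET1, CMT3, DDM1, ROS1, SDC, CCA1, LHY, TOC1, GI, FLC, FT, BRCA1, AOX1A and PR1. It adds up to 8 called genes that rose and 8 that fell with the largest changes, with a mean of at least 5 CPM, a reference symbol and no overlap between the replicates of the compared groups. It also adds up to 4 called members of each list with at least 3 called members or a list call. Any other gene named was chosen after its values were seen, and the text says so. For familiar genes the usual name is given; the reference calls DDM1 CHR1, ROS1 DML1, PR2 BGL2, JAZ2 TIFY10B, JAZ9 TIFY7, RVE7 EPR1, RVE4 LCL1, SOC1 AGL20, MAF2 AGL31, BASS5 BAT5, KN SYP111 and CYCB1;2 CYC1BAT, and gives no symbol for SMR7, HSP23.5, ROF2, LNK1 and UPOX.

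The alternatives were no filter on low counts, a stricter filter of 1 CPM in 5 replicates, DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, organelle genes left out, only the groups of each contrast in the fit, the replicate number as a block, the first technical library alone, limma voom on the 26 libraries with the biological replicate as a random effect, the 26 libraries taken as independent, camera on ranks, an estimated correlation for the lists, and each replicate left out in turn. The voom fit had a consensus correlation of 0.506 between technical libraries. A further alternative, chosen after the data were seen, left out genes with over 50% of their exon bases under an exon of the opposite strand. Overlaps of exons were found with GenomicRanges 1.54.1. DESeq2 size factors moved the median log2 fold change of all genes by at most 0.0142 in size, in the difference between both responses.

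The fits were tested on simulated counts of the 22031 genes with 200 genes changed. With edgeR, 54% of the 2-fold changes and 87% of the 4-fold changes were recovered in memory line against wild type, 57% and 92% in azacytidine against none in wild type, 54% and 81% in azacytidine against none in the memory line, 24% and 71% for the difference between the responses, and 44% and 84% in memory line against wild type on azacytidine. Unchanged genes made up 2.8%, 7.5%, 6.2%, 11.2% and 8.6% of the simulated edgeR calls in that order, and 14.7%, 15.4%, 12.7%, 19.9% and 17.8% of those of DESeq2. Of 200 simulated lists of 20 unchanged genes, camera with the preset correlation gave an unadjusted p under 0.05 for 2, 1, 2, 6 and 6. These genes were simulated independently and the lists drawn at random. The simulation therefore cannot tell whether the preset correlation is high enough for lists whose members move together. Splits of the untreated wild-type controls with no effects were simulated 50 times with independent genes and 1000 times with the correlation between genes kept, after the result was seen.

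Libraries held 2224933 to 9335587 gene counts, with a median of 4255920. A count of 0 allows up to 3 counts, which is 0.221 to 0.263 CPM per biological replicate. Where every replicate of a group was at 0 counts, a fold was computed against the mean floor of 3 counts per replicate and is a lower bound. Where the replicates held 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only. The sources used here do not say whether reads were counted by strand; for genes overlapped by exons of the opposite strand the reads of both strands cannot be told apart.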

Results

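Gene expression was measured by RNA sequencing in 10-day-old Arabidopsis plants of 2 genotypes, wild type and an msh1 memory line, grown with 0 or 100 µM 5-azacytidine. The memory line descends from plants in which MSH1, a gene for a DNA-binding protein of mitochondria and plastids, had been suppressed. The 4 groups held 3 replicates of untreated wild type, 3 of treated wild type, 2 of the untreated memory line and 2 of the treated memory line. Summed over 2 or 3 technical libraries, the replicates held 12548668, 12828449 and 13116891 gene counts in wild type and 13544859, 13079096 and 12689700 in treated wild type. They held 12854035 and 11412839 in the memory line and 12522071 and 12518386 in the treated memory line. Reads in no gene made up 48.2% to 49.3% of the uniquely aligned reads of each library. In memory-line replicate 2, 25.7% of the reads had aligned to more than 1 place, against 6.49% to 13.6% in the other replicates.

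On the first principal component of log2 CPM, which held 35.2% of the variance of 13980 genes, untreated wild type lay at the low end and treated plants at the high end. Wild-type replicates 1 and 2 stood at -37.4 and -32.9, while replicate 3 stood at -9.69, close to memory-line replicate 2 at -8.98. The second component, with 25.1% of the variance, set the memory line apart from wild type in both treatments.

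**Figure D1:**
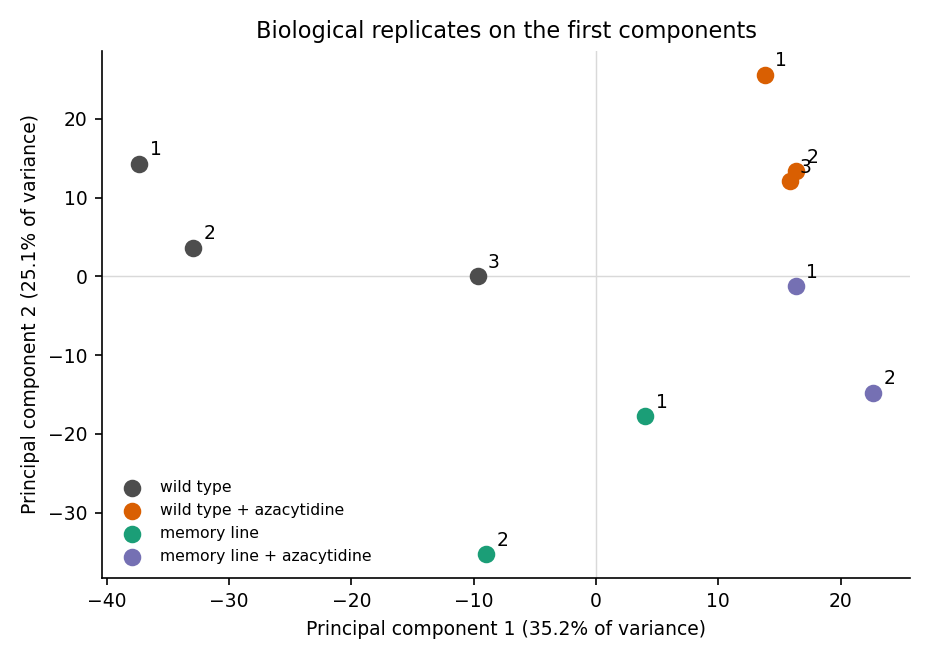
Scores of the 10 biological replicates on the first and second principal components of log2 CPM of 13980 genes, with the share of variance on each axis; each point is 1 replicate, coloured by group. Wild-type replicate 3, at -9.69 on the first component, lies apart from replicates 1 and 2, at -37.4 and -32.9.

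MSH1 (AT3G24320) was expressed in all groups and was called in no comparison. Its level was 10.7 ± 2.9 CPM in wild type, 15.5 ± 4.3 in treated wild type (SD, n = 3 each), 11.98 ± 1.93 in the memory line and 13.9 ± 1.05 in the treated memory line (SD, n = 2 each). The log2 fold change in memory line against wild type was 0.16 (SE 0.25, edgeR adjusted p = 0.820). It was 0.52 (SE 0.22, adjusted p = 0.175) on azacytidine in wild type and 0.21 (SE 0.27, adjusted p = 0.895) in the memory line, and the difference between both responses was -0.31 (SE 0.35, adjusted p = 0.834). Between the treated genotypes it was -0.15 (SE 0.25, adjusted p = 0.849). Without wild-type replicate 3, MSH1 was called in the wild-type response, at 0.78 (adjusted p = 0.0402), and limma voom on the 26 libraries called it at 0.53.

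The first comparison asked how wild type responded to azacytidine. Of 8 tested loci silenced by methylation or imprinted 3 rose: SDC, an F-box gene silenced through methylated repeats, rose from 0.383 ± 0.242 to 8.64 ± 0.436 CPM (SD, n = 3 each), and the orphan gene QQS rose from 1.99 ± 1 to 31.1 ± 6.57 CPM. FWA, an imprinted homeobox gene, had 0 counts in every untreated wild-type replicate and reached 4.47 ± 3.75 CPM, at least 19-fold higher. Of 29 jasmonate genes 15 fell, among them JAZ7 from 25.5 ± 10.3 to 1.42 ± 0.462 CPM. Outside that list ILL6, which breaks down active jasmonate, fell from 36.2 ± 8.49 to 3.61 ± 0.583 CPM. Of 33 DNA damage genes 6 rose, among them PARP2, a poly(ADP-ribose) polymerase, from 6.28 ± 1.08 to 21.9 ± 3.47 CPM.

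In edgeR 1408 of the 22031 genes changed, 665 upward and 743 downward, and 267 and 283 of these by at least 2-fold. Of the genes that rose 73 were noncoding, and of those that fell 26 were. Among the 1408 genes called, coding and noncoding together, 106 had over 50% of their exon bases under exons of the opposite strand. The reads of both strands cannot be told apart for these genes, so noncoding calls among them may repeat a change of the opposite gene. The log2 fold change was 4.44 for SDC (SE 0.36, adjusted p = 1.81e-05), 3.97 for QQS (SE 0.45, adjusted p = 0.00163), -4.16 for JAZ7 (SE 0.39, adjusted p = 0.000329), -3.32 for ILL6 (SE 0.26, adjusted p = 4.26e-05) and 1.80 for PARP2 (SE 0.28, adjusted p = 0.00417). FWA had an adjusted p of 0.0258. Exons of the opposite strand cover 80.2% of the exon bases of SDC, so its reads are uncertain as to strand. The number of calls was 530 without wild-type replicate 1, 439 without replicate 2 and 2500 without replicate 3. It was 432, 484 and 835 without treated wild-type replicates 1, 2 and 3, and of the 52 genes named by the rule and called here, 22, 28, 4, 26, 27 and 14 lost their call in these 6 settings.

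Besides SDC, QQS and FWA no silenced locus was called over all genes; 4 rose and 1 fell adjusted over the list alone. Their median log2 change was 1.21, also with FWA at its bound, and the list was called upward (adjusted p = 0.0156; adjusted p = 0.460 with an estimated correlation). That call was lost without a filter on low counts (median 0.15, adjusted p = 0.116), on ranks (0.115) and without genes overlapped by antisense exons (median 0.40, 0.120). The median was 3.48 without wild-type replicate 3, 2.01 with the stricter filter and 3.01 with the first technical library alone. Among the 32 genes of the methylation and silencing machinery, only DMS3, chosen after its values were seen and with 54.6% under antisense exons, so uncertain as to strand, rose, by 0.62 (adjusted p = 0.0355, kept in 11 of 16 alternatives), and none did adjusted over the list alone. That list was not called (median 0.22, adjusted p = 0.0691). The methyltransferase genes MET1 (0.37, adjusted p = 0.110) and CMT3 (0.42, 0.178), the remodeller gene DDM1 (0.32, 0.344) and the demethylase gene ROS1 (-0.46, 0.0776) did not pass the test.

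Jasmonate genes made up the list with the smallest p in this comparison. Of 29 genes 15 fell and none rose, or 19 fell and 1 rose adjusted over the list alone, and the median was -1.35 (adjusted p = 3.65e-11; adjusted p = 0.460 with an estimated correlation). JAZ2 (-1.60, SE 0.14, adjusted p = 2.78e-05), JAZ5 (-2.28) and JAZ7, all repressors of jasmonate signalling that jasmonate itself induces, fell together with MYC2 (-1.49), a transcription factor gene of this pathway. Antisense exons cover 98.5% of MYC2, so its reads are uncertain as to strand. The genes with the largest falls also held SEN1 (-4.03) and ASN1 (-3.39), which darkness and low sugar induce, and CYP81D11 (-3.02), HMT3 (-2.84), SIS (-2.81) and FAMT (-2.62).

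Of 23 glucosinolate genes 7 fell, 12 adjusted over the list alone, with a median of -0.47 (adjusted p = 1.07e-05; 0.495 as the adjusted p with an estimated correlation). Named members were MYB29 (-1.195), a regulator of aliphatic glucosinolates, BASS5 (-0.90), SOT18 (-0.86) and GSTF11 (-1.59), whose exons antisense exons cover in full. In the heat shock list 3 of 16 genes fell, HSP23.5 (-1.47), ROF2 (-1.11) and GOLS1 (-0.81), or 6 adjusted over the list alone (median -0.69, adjusted p = 0.00180; adjusted p = 0.495 with an estimated correlation). Root markers moved the same way: 6 of 22 fell, or 7 with 1 that rose adjusted over the list alone (median -0.54, adjusted p = 0.00160; adjusted p = 0.367 with an estimated correlation). They included CASP2 (-1.40), CASP1 (-1.01), PER64 (-1.16) and ESB1 (-0.74), genes of the Casparian strip of the endodermis; antisense exons cover 84.3% of ESB1.

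The DNA damage list rose, with 6 of 33 genes up and none down, 16 up adjusted over the list alone, and a median of 0.57 (adjusted p = 4.50e-07; adjusted p = 0.495 with an estimated correlation). Other called members were SMR7 (2.97, adjusted p = 0.00243), a cell cycle inhibitor gene, TK1A (0.90) and XRI1 (0.72). BRCA1 had a log2 change of 0.71 and was not called (adjusted p = 0.157). All 15 mitosis genes were higher and 3 rose, 4 adjusted over the list alone (median 0.35, adjusted p = 0.000344; adjusted p = 0.599 with an estimated correlation). These were CYCB1;4 (0.71), CYCB1;2 (0.60) and KN (0.51), 33.5% of which lies under antisense exons. Of 12 DNA replication genes MCM4 (0.56) rose, and 4 did adjusted over the list alone (median 0.49, adjusted p = 0.00275; adjusted p = 0.644 with an estimated correlation).

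Immunity genes of the salicylate list were split: PR2 (5.50, SE 1.02, adjusted p = 0.0298), a glucanase gene, AIG1 (2.94) and SAG101 (0.79) rose and EDS5 (-0.54) fell, and 4 of 23 rose and 1 fell adjusted over the list alone. PR1 was at 48.9 ± 38.7 CPM against 4.34 ± 7.39 (SD, n = 3 each) and was not called (adjusted p = 0.199). The salicylate list was called upward (median 0.17, adjusted p = 0.0475; adjusted p = 0.792 with an estimated correlation), but not without wild-type replicates 2 (adjusted p = 0.0673) or 3 (0.491, median 0.01), without treated replicate 1 (0.368, median -0.08), with the stricter filter (0.0714) or on ranks (0.0698); the median was 0.60 without wild-type replicate 1 and 0.36 without treated replicate 3. The other genes with the largest rises were PCR1 (7.41, SE 1.37, adjusted p = 0.0285; an uncertain size, with 6, 0 and 0 counts in untreated replicates, 6.45 to 11.50 over the alternatives and the call kept in 14 of 17), MRU1 (3.76), NAC103 (1.81), RLP34 (1.695) and UF3GT (1.65).

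Another 4 lists were called in wild type and lost the call without single replicates. Of 14 morning clock genes 3 fell, RVE7 (-1.45), RVE4 (-0.62) and RVE2 (-0.61), or 6 with 1 that rose adjusted over the list alone (median -0.60, adjusted p = 0.0296; adjusted p = 0.644 with an estimated correlation). This call was lost without wild-type replicates 2 (adjusted p = 0.190, median -0.25) or 3 (0.0587) and without treated replicate 1 (0.0507, median -0.40). In the flowering list SPL3 (-1.30, with 97.3% under antisense exons), SOC1 (-0.60), MAF3 (-0.56) and MAF2 (-0.49) fell, 4 of 20, or 6 with 1 that rose adjusted over the list alone. Its median was -0.30 while its mean was 0.09, and its downward call (adjusted p = 0.0355; adjusted p = 0.505 with an estimated correlation) was lost on ranks (0.0801), without treated replicate 2 (0.201) and without genes overlapped by antisense exons (0.0624). Of 18 flavonoid genes UF3GT rose, and 1 did adjusted over the list alone (median 0.37, adjusted p = 0.0463; adjusted p = 0.792 with an estimated correlation), a call lost without wild-type replicates 1 (0.0732) or 2 (0.0708) or treated replicates 1 (0.0719) or 3 (0.100); the median was 0.21 with the stricter filter. None of 20 early wound genes changed, in edgeR or adjusted over the list alone (median -0.55, adjusted p = 0.0475; adjusted p = 0.792 with an estimated correlation). Its call was lost without wild-type replicate 1 (0.492, median -0.23) or treated replicates 2 (0.152) or 3 (0.346, median -0.33), and the median was -0.85 without treated replicate 1.

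The remaining 9 lists were not called in wild type. Among abscisic acid genes RD20 (-2.14), RD26 (-2.02) and ABF4 (-0.51) fell, 3 of 22 by both adjustments (median -0.16, adjusted p = 0.348). The next 4 genes were chosen after their values were seen; ERF1, ERF2, UGT74E2 and GH3.3 kept their call in 8 of 10, 10 of 17, 13 of 17 and 17 of 17 alternatives. ERF1 (-3.12, to 8, 2 and 1 counts, and -4.32 to -2.70 over the alternatives) and ERF2 (-1.43), transcription factor genes induced by ethylene, fell among 12 ethylene genes, 3 adjusted over the list alone (median -0.30, adjusted p = 0.0652). UGT74E2 (-1.33) and HSP23.5 fell among 16 mitochondrial stress genes, 2 by both adjustments (-0.19, 0.197), and GH3.3 (1.27) rose among 15 auxin genes, 1 by both adjustments (0.14, 0.239). No cold gene was called over all genes and 3 of 13 rose adjusted over the list alone (0.35, 0.110). Iron deficiency (-0.41, 0.177), photosynthesis (0.07, 0.471), evening clock (0.03 with a mean of -0.04, 0.707) and phosphate starvation genes (0.24 with a mean of -0.08, 0.540) had no member called by either adjustment.

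**Figure D2:**
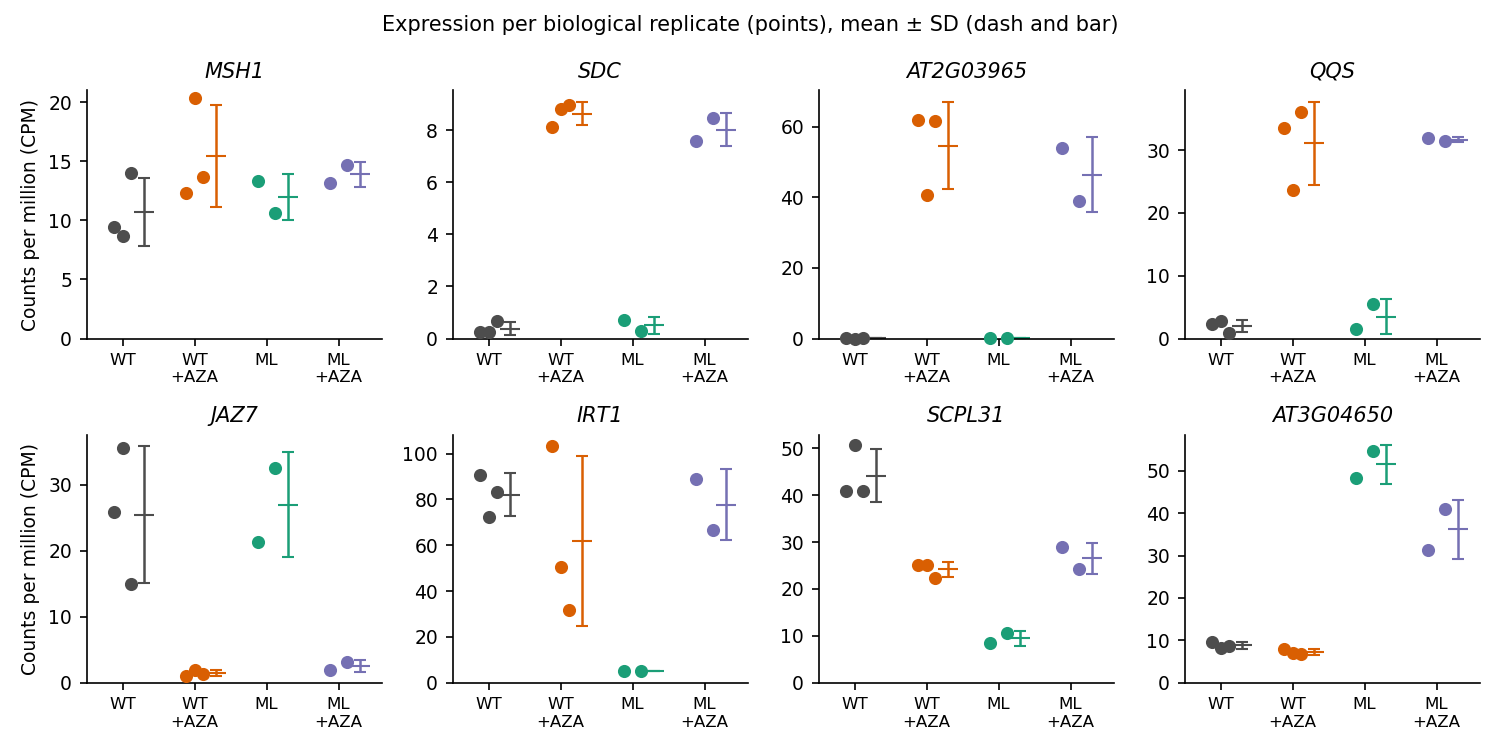
CPM of 8 genes (MSH1, SDC, AT2G03965, QQS, JAZ7, IRT1, scpl31 and AT3G04650) in each biological replicate, as points, with mean and SD per group; WT is wild type, ML the memory line and AZA azacytidine. SDC lies at 8.64 CPM in treated and 0.383 CPM in untreated wild type, and IRT1 at 5.25 CPM in the untreated memory line against 82.1 CPM in untreated wild type.

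The second comparison asked how the memory line responded to azacytidine. As in wild type, SDC rose, from 0.500 ± 0.308 to 8.01 ± 0.633 CPM (SD, n = 2 each), and QQS from 3.48 ± 2.79 to 31.7 ± 0.424 CPM. Of 29 jasmonate genes 10 fell, among them JAZ9 from 161 ± 64.6 to 24.0 ± 2.74 CPM, JAZ7 from 27.0 ± 7.94 to 2.50 ± 0.895 CPM and VSP2, a storage protein gene induced by jasmonate, from 119 ± 49.4 to 22.2 ± 4.43 CPM. Genes with large rises were IRT1, the main iron transporter of the root, from 5.25 ± 0.0184 to 77.8 ± 15.6 CPM, NAS2, for a nicotianamine synthase, from 4.15 ± 0.903 to 40.7 ± 5.45 CPM, and MTPA2, for a metal transporter of the vacuole, from 5.56 ± 1.98 to 16.95 ± 1.28 CPM.

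In edgeR 163 genes changed, 105 upward and 58 downward, and 103 and 49 by at least 2-fold. The log2 fold change was 3.92 for SDC (SE 0.43, adjusted p = 0.000573), -2.74 for JAZ9 (SE 0.31, adjusted p = 0.00205), 3.89 for IRT1 (SE 0.55, adjusted p = 0.0232) and 3.304 for NAS2 (SE 0.28, adjusted p = 9.07e-05). IRT1 kept its call in only 9 of 15 alternatives, with log2 fold changes of 3.64 to 4.06. SDC, JAZ9 and NAS2 kept theirs in every alternative that gave a value. The other genes with the largest rises were MRU1 (3.76), QQS (3.24), PP2-A8 (2.31), PP2-A6 (1.86), MTPA2 (1.62) and GLYI4 (1.58). Besides JAZ genes and VSP2, the largest falls were those of FAMT (-4.17), ATSDI1 (-2.49), ILL6 (-2.34), HMT3 (-2.27) and AOC1 (-2.24). Without memory-line replicates 1 and 2 the count was 283 and 104, without treated replicate 1 it was 91, and DESeq2 called 384. Of the 24 genes named by the rule and called here, 4, 11, 15 and 10 lost their call without memory-line replicates 1 and 2 and treated replicates 1 and 2.

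All 29 jasmonate genes were lower in the treated memory line; 10 fell, 19 adjusted over the list alone (median -1.62, adjusted p = 2.28e-23; adjusted p = 0.305 with an estimated correlation). JAZ6 (-1.699) was a further named member. Of the 8 silenced loci SDC and QQS rose, 5 adjusted over the list alone (median 3.11, adjusted p = 0.000344; adjusted p = 0.305 with an estimated correlation). Of 23 glucosinolate genes CYP79B2 (-0.80) and MYB34 (-0.81) fell, 10 adjusted over the list alone (median -0.46, adjusted p = 4.50e-07; adjusted p = 0.495 with an estimated correlation). Both clock lists were lower: LNK1 (-1.25) fell among 14 morning genes, 5 adjusted over the list alone (median -1.16, adjusted p = 4.50e-07; adjusted p = 0.460 with an estimated correlation). None of the 11 evening genes changed over all genes, all were lower and 7 fell adjusted over the list alone (median -0.57, adjusted p = 1.72e-06; adjusted p = 0.495 with an estimated correlation). Without memory-line replicate 2 the medians of morning and evening clock genes were -0.66 and -0.30, and without replicate 1 that of evening clock genes was -0.87.

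Of 15 iron deficiency genes IRT1 and ABCG37 (0.95), an exporter of phenolic compounds, rose, 5 adjusted over the list alone; the median was 0.34 (adjusted p = 0.00275; adjusted p = 0.644 with an estimated correlation). The iron call was lost on ranks (0.184) and without treated memory-line replicate 1 (0.122, median -0.10); the median was 0.20 and 0.65 without memory-line replicates 1 and 2, 0.81 without treated replicate 2 and 0.21 with the first technical library alone. Root markers, which share IRT1 and FRO2 with that list, had a median of -0.44 and a mean of 0.20 and were not called (adjusted p = 0.122); 1 of 22 rose, and 3 rose and 5 fell adjusted over the list alone. SMR7 (3.00) rose among 33 DNA damage genes, 6 adjusted over the list alone (median 0.39, adjusted p = 3.19e-06; adjusted p = 0.515 with an estimated correlation), a call lost without memory-line replicate 2 (0.0514, median 0.18), while the median was 0.75 without replicate 1. ALD1, needed for pipecolic acid synthesis, rose 9.07-fold (95% counting interval 3.62 to 29.2) from 3 and 2 counts in untreated replicates 1 and 2. It kept its call in 9 of 15 alternatives. The salicylate list was called upward (median 0.46, adjusted p = 0.00955; adjusted p = 0.745 with an estimated correlation), but not without memory-line replicate 2 (0.762, median 0.23) or treated replicate 1 (0.0894, median 0.09); the median was 0.93 without memory-line replicate 1.

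Of the remaining lists 5 were called in the memory line with no member called over all genes. Abscisic acid (median -0.57, adjusted p = 2.86e-05; 0.495 as the adjusted p with an estimated correlation) and flowering genes (-0.16, 0.00427; 0.495 as the adjusted p with an estimated correlation) lost the call without memory-line replicate 2 (0.0557 and 0.0720, medians -0.15 and -0.09). Without replicate 1 these medians were -0.88 and -0.28, and that of flowering genes was -0.09 and -0.25 without treated replicates 1 and 2 and -0.31 with the first technical library alone. Phosphate starvation genes, all 9 of them lower (-0.70, 0.00192; 0.562 as the adjusted p with an estimated correlation), lost it without memory-line replicate 1 (0.254, median -0.185) or treated replicate 2 (0.319, median -0.33), and had a median of -1.31 without treated replicate 1. Mitosis genes (0.25, 0.0250; 0.776 as the adjusted p with an estimated correlation) lost it without memory-line replicate 2 (0.357, median 0.13) or treated replicate 2 (0.466, median 0.125), and had a median of 0.38 without memory-line replicate 1. Of 34 photosynthesis genes 31 were lower (-0.34, 0.00427; 0.792 as the adjusted p with an estimated correlation), and the median turned to 0.33 without memory-line replicate 2 and to 0.10 without treated replicate 2, and was -0.82 and -0.92 without memory-line replicate 1 and treated replicate 1. Adjusted over the list alone, 2 abscisic acid genes, 3 flowering genes, 1 phosphate gene and no mitosis or photosynthesis gene fell.

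The lists not called in the memory line were early wound (median 0.53, adjusted p = 0.0549), flavonoid (0.20, 0.0502), DNA replication (0.28, 0.0647), cold (-0.37, 0.107), ethylene (-0.12, 0.422), mitochondrial stress (0.17, 0.579) and methylation machinery (0.02, 0.657, with a mean of -0.03) lists. Of these, adjusted over the list alone, 1 ethylene gene rose, and 1 ethylene gene and 1 cold gene fell. Auxin genes had a median of -0.09 and a mean of 0.04 (0.686), and heat shock genes a median of 0.07 with a downward statistic (0.797). ROS1 (-0.64, adjusted p = 0.175), GI (-1.01, 0.292), TOC1 (-0.57, 0.241) and CCA1 (-1.71, 0.549) did not pass the test.

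The responses of both genotypes were then set side by side; they share no library. Of the 1408 genes called in wild type, 1145 (81.3%) had the same sign in the memory line. Of these 78 rose in both, against 3.17 expected for independent lists, and 43 fell in both, against 1.96. Only scpl31 was called in opposite directions. Across all genes the fold changes had a Pearson r of 0.654 and a Spearman rho of 0.302, where genes are not independent replicates. The share of same-sign genes was 70.6% without memory-line replicate 2 and 90.08% without treated wild-type replicate 2. The number of calls differed between the genotypes with 3 replicates against 2, and only the interaction, given last, tests whether a gene's response differed.

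**Figure D3:**
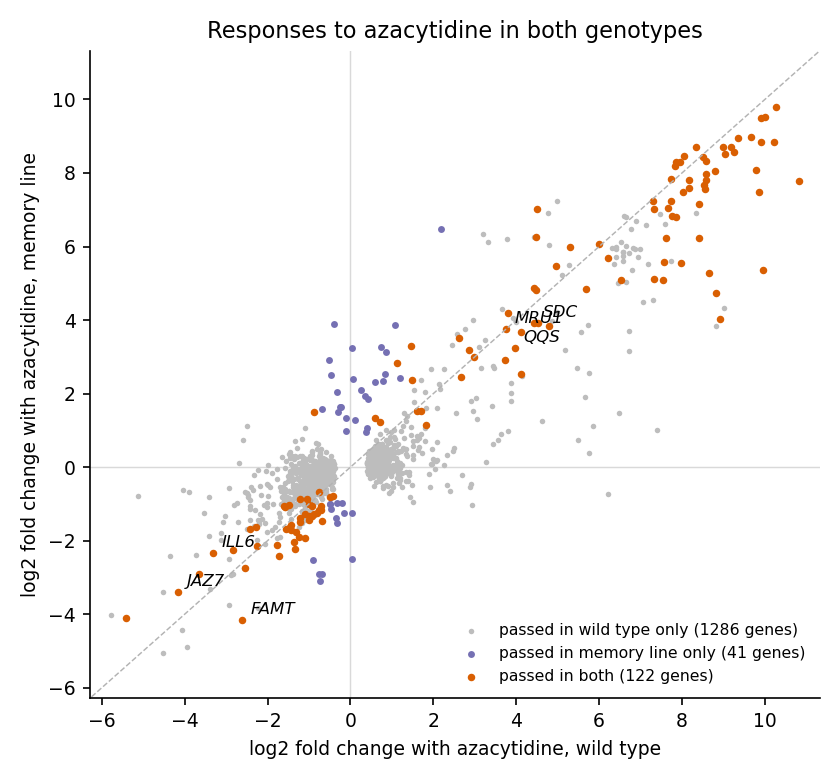
Log2 fold change on azacytidine in wild type (horizontal) and in the memory line (vertical) for genes called in at least 1 of both responses, coloured by where a gene was called; the dashed line marks equal changes. Of the genes called in both, 78 rose in both and 43 fell in both; fold changes of genes with 0 to 3 untreated counts depend on the small count that the fit adds.

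Many of the 78 genes that rose in both genotypes were off without the drug. Of these 78 genes 65 are coding and 13 noncoding, and 48 had at most 3 counts in every untreated replicate, 28 of them 0. Antisense exons cover over 50% of the exon bases of 10 of the 78. The next 4 genes were chosen after their values were seen. AT3G44265 (chromosome 3, 15955138 to 15956246 in TAIR10.1) went from 0 counts in all 5 untreated replicates to 12.1 ± 1.56 CPM in wild type (SD, n = 3) and 8.66 ± 0.952 in the memory line (SD, n = 2), at least 51.3-fold and at least 34.9-fold higher. AT3G01345 rose from 0.348 ± 0.219 to 55.1 ± 10.7 CPM in wild type and from 0.334 ± 0.339 to 56.6 ± 1.43 CPM in the memory line. AT2G03965 (chromosome 2, 1251510 to 1252989) reached 54.6 ± 12.2 and 46.4 ± 10.7 CPM, a ratio of 1050 in wild type (95% counting interval 290 to 8660) and 282 in the memory line (110 to 1040). It overlaps the noncoding gene AT2G04655 on the opposite strand, and their reads cannot be told apart. These genes kept their call in all alternatives that gave a value.

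**Figure D4:**
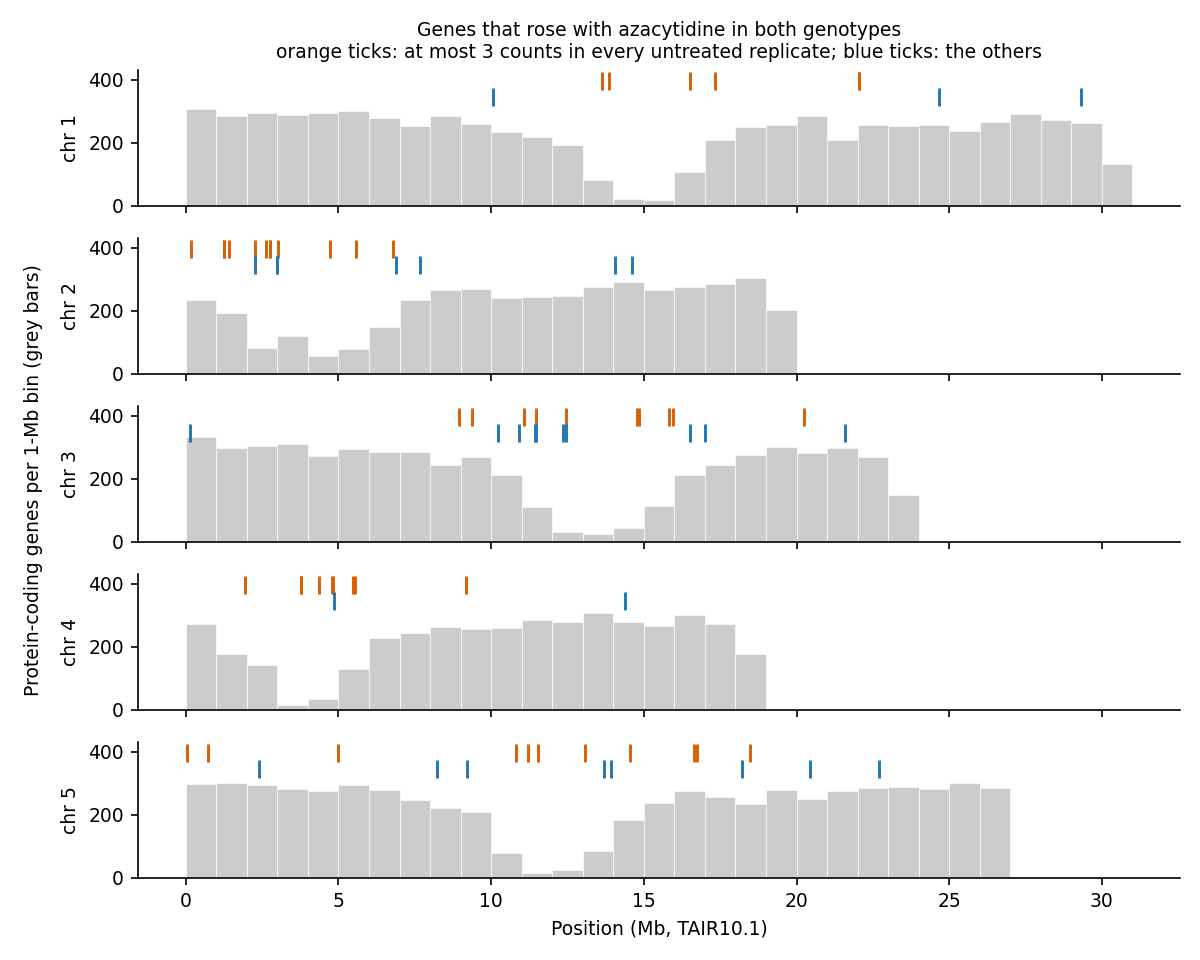
Positions in TAIR10.1 of the genes that rose on azacytidine in both genotypes along the 5 chromosomes, with grey bars for the number of coding genes per 1-Mb bin; orange ticks mark genes with at most 3 counts in every untreated replicate and blue ticks the others. The 78 genes had a median of 78 coding genes within 250 kb, against 136 for all tested genes.

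The third comparison asked how the memory line differed from wild type without the drug. The iron uptake genes IRT1 and FRO2 were far lower in the memory line: IRT1 fell from 82.1 ± 9.34 CPM in wild type (SD, n = 3) to 5.25 ± 0.0184 CPM (SD, n = 2), and FRO2, the ferric chelate reductase gene, from 54.1 ± 9.17 to 2.22 ± 0.614 CPM. The immunity gene ALD1 was lower, at 0.202 ± 0.0193 against 1.58 ± 0.3 CPM, as was the chaperone gene HSP90.1, at 6.33 ± 1.5 against 20.6 ± 1.41 CPM. FLN1 and FLN2, fructokinase-like proteins of the plastid transcription machinery, were higher, FLN2 at 113 ± 6.08 against 49.1 ± 12.5 CPM. The serine carboxypeptidase-like gene scpl31 fell from 44.2 ± 5.69 to 9.51 ± 1.57 CPM.

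In edgeR 258 genes changed, 153 upward and 105 downward, and 50 and 78 by at least 2-fold. The log2 fold change was -3.96 for IRT1 (SE 0.54, adjusted p = 0.0226), -4.58 for FRO2 (SE 0.71, adjusted p = 0.0358), -2.22 for scpl31 (SE 0.17, adjusted p = 5.06e-05) and 1.202 for FLN2 (SE 0.17, adjusted p = 0.00983). IRT1, FRO2, ALD1 and FLN2 kept their call in 12, 10, 9 and 14 of 16 alternatives, and scpl31 in all 16. The log2 fold change ran from -4.18 to -3.65 for IRT1 and from -4.92 to -4.345 for FRO2 over these alternatives. The other genes with the largest rises were EMB2729 (1.39), SCPL9 (1.19), XDH2 (1.12), SDR4 (1.095), FUC1 (1.07), FLN1 (1.06) and PHO1;H1 (1.03). The largest falls also held MES18 (-2.05), OXS3 (-2.04), PP2-A8 (-1.99), BT5 (-1.87) and LHCB4.3 (-1.85). AT3G04650, chosen after its values were seen, had the smallest p, at 51.5 ± 4.54 against 8.84 ± 0.766 CPM (2.54, SE 0.16, adjusted p = 6.07e-06). The count was 32, 33 and 891 without wild-type replicates 1, 2 and 3, 92 without memory-line replicate 2 and 904 with DESeq2. It was 39 with only both untreated groups in the fit. Of the 21 genes named by the rule and called here, 13, 16, 9 and 12 lost their call without wild-type replicates 1 and 2 and memory-line replicates 1 and 2.

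All 15 iron deficiency genes were lower in the memory line, 2 fell over all genes and 4 adjusted over the list alone (median -1.07, adjusted p = 1.83e-07; adjusted p = 0.495 with an estimated correlation). Root markers, which hold IRT1 and FRO2 too, were lower with them: 17 of 22 were lower, and these 2 fell, with 2 down and 1 up adjusted over the list alone (median -0.34, adjusted p = 0.00427; adjusted p = 0.405 with an estimated correlation). Of 23 salicylate immunity genes 20 were lower; ALD1 fell, with a ratio of 7.83 (95% counting interval 3.18 to 25), and 4 fell adjusted over the list alone (median -0.96, adjusted p = 9.38e-07; adjusted p = 0.495 with an estimated correlation). Of 20 early wound genes 18 were lower; CYP81F2 (-1.49), of indole glucosinolate synthesis, fell, and 5 did adjusted over the list alone (median -0.97, adjusted p = 3.61e-06; adjusted p = 0.513 with an estimated correlation). In the heat shock list HSP23.5 (-1.89), HSP90.1 (-1.69) and ROF2 (-1.49) fell, 3 of 16, and 7 adjusted over the list alone (median -0.90, adjusted p = 1.25e-05; adjusted p = 0.405 with an estimated correlation). None of 23 glucosinolate genes changed over all genes, while 9 fell and 1 rose adjusted over the list alone (median -0.61, adjusted p = 0.000367; adjusted p = 0.513 with an estimated correlation). The salicylate median was -1.87 without memory-line replicate 1, the early wound median -0.63 without wild-type replicate 1, and the glucosinolate median -0.33 without wild-type replicate 2 or memory-line replicate 2 and -0.91 without memory-line replicate 1.

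The other 3 list calls rested on single replicates. Of 12 ethylene genes 11 were lower and none was called by either adjustment (median -0.42, adjusted p = 0.00475; adjusted p = 0.495 with an estimated correlation); the call was lost without wild-type replicate 1 (0.0782, median -0.165) or memory-line replicate 2 (0.0765), and the median was -0.27 without wild-type replicate 2. All 11 evening clock genes were higher and none was called by either adjustment (median 0.32, adjusted p = 0.0186; adjusted p = 0.644 with an estimated correlation), a call lost without wild-type replicate 1 (0.0599) or memory-line replicate 2 (0.590, median 0.03), while the median was 0.48 without memory-line replicate 1. Of 33 DNA damage genes none was called over all genes and 4 rose adjusted over the list alone (median 0.23, adjusted p = 0.00570; adjusted p = 0.753 with an estimated correlation). Without memory-line replicate 1 its median was 0.005 (adjusted p = 0.871) and its statistic turned downward; without replicate 2 it was 0.39.

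Single called genes stood in lists that were not called; RVE2, LFY and UPOX were chosen after their values were seen and kept their call in 12 of 16, 4 of 12 and 13 of 16 alternatives. LFY lost it whichever replicate of these groups was left out. RVE2 fell (-0.92, adjusted p = 0.0243) among the morning clock genes, with a list median of 0.08 and a downward statistic (adjusted p = 0.787). LFY, a floral regulator gene, rose from 0.234 ± 0.0754 to 1.46 ± 0.0684 CPM (adjusted p = 0.0459) in the flowering list, whose median was 0.00 and mean 0.42 (adjusted p = 0.452). UPOX, for a mitochondrial protein induced by oxidative stress, rose (1.69, adjusted p = 0.0119) and HSP23.5 fell in the mitochondrial stress list (median 0.03, mean -0.35, adjusted p = 0.714). The jasmonate (median -0.01, adjusted p = 0.622), auxin (-0.20, 0.122) and phosphate starvation lists (-0.19, 0.579) had no member called over all genes and were not called, nor were the methylation machinery (0.13, 0.180), flavonoid (0.20, 0.148), mitosis (0.10, 0.290), DNA replication (0.10, 0.422), abscisic acid (0.15, 0.348), cold (0.38, 0.372) and photosynthesis lists (0.13, 0.555). Adjusted over the list alone, 1 jasmonate gene, 1 abscisic acid gene, 1 flavonoid gene and 2 mitochondrial stress genes rose, and 3 jasmonate, 2 abscisic acid and 2 mitochondrial stress genes fell. The silenced loci had a median of 0.20, or 0.03 with FWA at its bound, and a mean of -0.14 (0.579). SDC was at 0.500 ± 0.308 against 0.383 ± 0.242 CPM (adjusted p = 0.778).

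**Figure D5:**
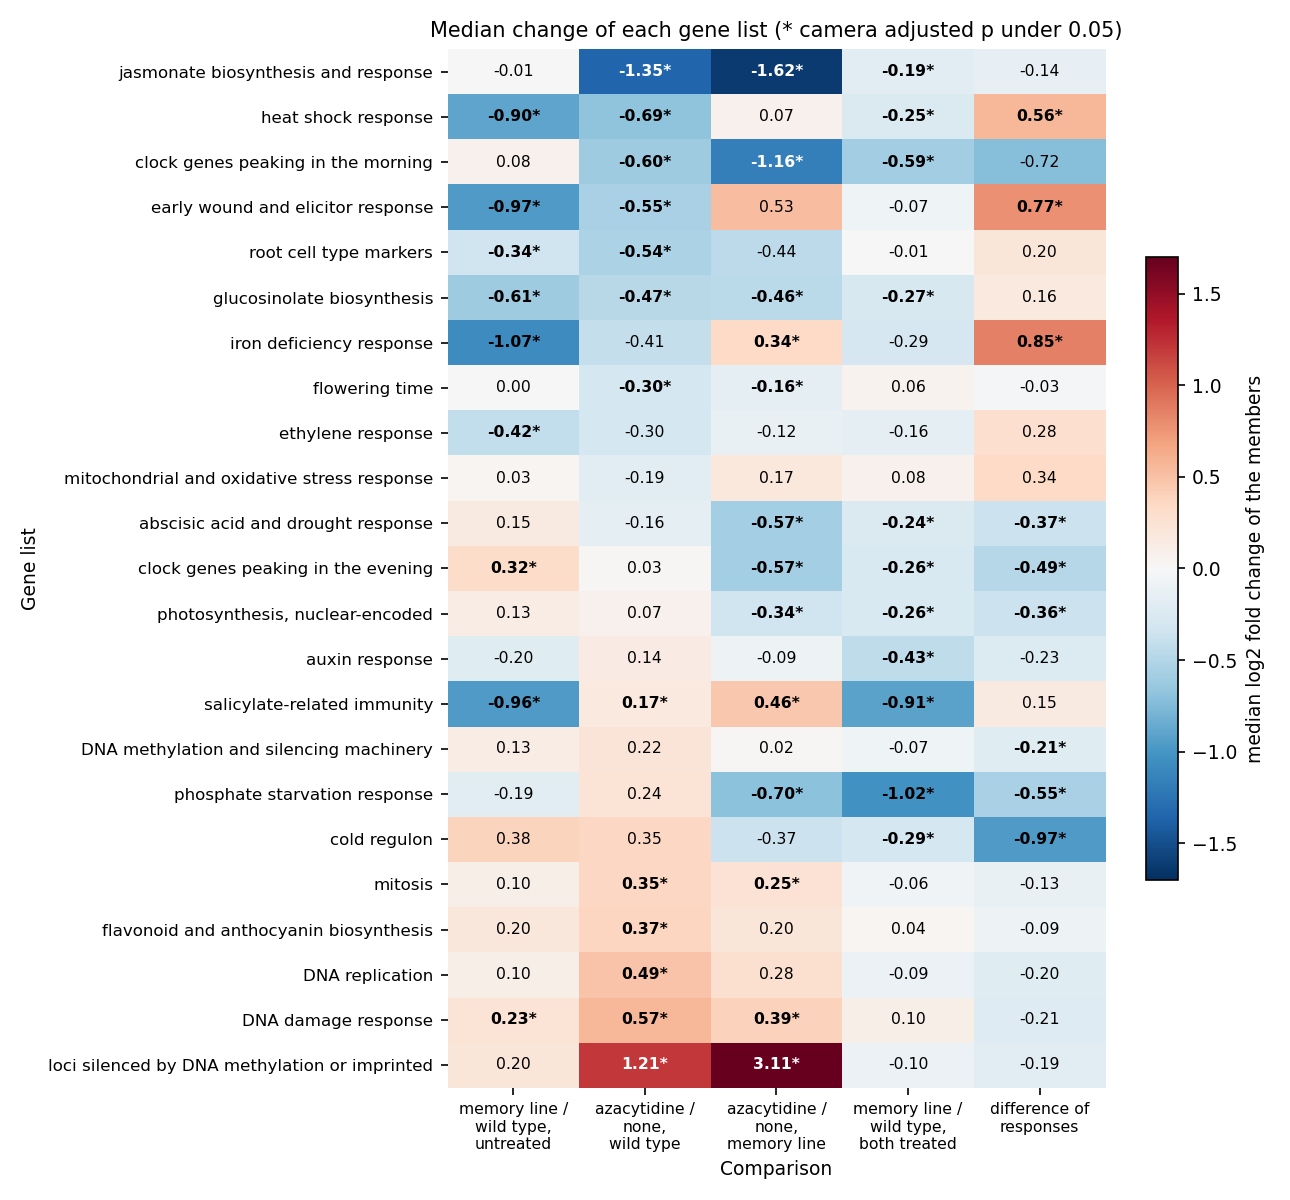
Median log2 fold change of the members of each of the 23 gene lists in the 5 comparisons, with an asterisk for lists called by camera with the preset correlation. Jasmonate genes have medians of -1.35 and -1.62 on azacytidine in wild type and the memory line, and iron deficiency genes a median of -1.07 in the untreated memory line; no list was called with an estimated correlation.

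The fourth comparison set the treated memory line against treated wild type. AT3G04650 was higher here too, at 36.1 ± 6.87 CPM (SD, n = 2) against 7.26 ± 0.633 (SD, n = 3), as were UPOX, at 36.1 ± 2.54 against 6.23 ± 1.2 CPM, and G6PD4, a glucose-6-phosphate dehydrogenase gene, at 43.3 ± 7.54 against 22.1 ± 2.1 CPM. CYP707A2, whose product breaks down abscisic acid, was lower, at 2.55 ± 0.608 against 10.2 ± 2.48 CPM. The channel gene CNGC3 and the receptor kinase genes RLK and RK3 were lower as well. IRT1 was at 77.8 ± 15.6 against 61.8 ± 37.2 CPM.

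In edgeR 10 genes changed, 5 upward and 5 downward, while DESeq2 called 282 and 2656 genes had an unadjusted p under 0.05. G6PD4 (0.97, SE 0.15, adjusted p = 0.0407), CYP707A2 (-2.01, SE 0.30, adjusted p = 0.0407), CNGC3 (-1.25, SE 0.19, adjusted p = 0.0407), RLK (-1.197, SE 0.17, adjusted p = 0.0386) and RK3 (-1.81, SE 0.28, adjusted p = 0.0463) were named by the rule. The other 5 were chosen after their values were seen: AT3G04650 (2.31, SE 0.16, adjusted p = 2.46e-05), UPOX (2.54, SE 0.25, adjusted p = 0.00219), AT2G42170 (1.17), AT3G28540 (-2.75) and AT1G30170 (4.92, from 1, 4 and 2 counts in treated wild type, and 4.51 to 5.52 over the alternatives), which had 0 counts in untreated wild type. They kept their call in 16 of 16, 15 of 16, 9 of 16, 12 of 16 and 10 of 15 alternatives. The count was 2, 5 and 6 without treated wild-type replicates 1, 2 and 3, and 22 and 1 without treated memory-line replicates 1 and 2. Only both treated groups in the fit gave 203, and the 5 genes named by the rule lost 5, 3, 4, 4 and 5 calls in the 5 settings with a replicate left out.

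No list member except UPOX was called over all genes in this comparison, yet 11 lists were called downward. Of 23 salicylate immunity genes 22 were lower (median -0.91, adjusted p = 9.28e-08; adjusted p = 0.495 with an estimated correlation), and 6 fell and 1 rose adjusted over the list alone. PR1 was at 0.0850 ± 0.12 against 48.9 ± 38.7 CPM and was not called (adjusted p = 0.320). Phosphate starvation genes had 4 of 9 down adjusted over the list alone (median -1.02, adjusted p = 3.99e-05; adjusted p = 0.495 with an estimated correlation) and glucosinolate genes 7 of 23 (-0.27, 8.96e-05; 0.495 as the adjusted p with an estimated correlation). All 15 auxin genes were lower, 2 of them adjusted over the list alone (-0.43, 0.000176; 0.305 as the adjusted p with an estimated correlation). Morning clock genes had 2 of 14 down adjusted over the list alone (-0.59, 0.00180; 0.495 as the adjusted p with an estimated correlation). Without treated memory-line replicate 1 the phosphate and glucosinolate medians were -1.76 and -0.51, and without replicate 2 the auxin median was -0.29.

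The other 6 calls in the treated plants were lost without single replicates. Of 34 photosynthesis genes 32 were lower (median -0.26, adjusted p = 0.00183; adjusted p = 0.792 with an estimated correlation), and without treated memory-line replicate 2 the median was 0.19 (0.0584), against -0.935 without replicate 1. The cold (-0.29, 0.00427; 0.495 as the adjusted p with an estimated correlation), evening clock (-0.26, 0.0268; 0.644 likewise) and jasmonate calls (-0.19, 0.0363; 0.776 likewise) were lost without that replicate as well, with adjusted p = 0.281, 0.356 (median -0.13) and 0.757 (median -0.03). Without treated memory-line replicate 1 these medians were -0.55, -0.41 and -0.67, and without treated wild-type replicates 1 and 3 those of the cold list were -0.195 and -0.49. Without treated wild-type replicate 2 the evening clock call (0.127) and the jasmonate call (0.0822, median -0.10) were lost, and without replicate 1 (0.195, median -0.085) or with the stricter filter (0.0567, median -0.09) the jasmonate call; the jasmonate median was -0.31 without replicate 3. Adjusted over the list alone, 2 cold genes and 1 heat shock gene fell. The heat shock call (-0.25, 0.0462; 0.562 as the adjusted p with an estimated correlation) was lost on ranks (0.0665) and without treated wild-type replicates 1 (0.148) or 3 (0.0590) or treated memory-line replicates 1 (0.0566, median -0.475) or 2 (0.105, median -0.38), and the median was -0.38 with the stricter filter, -0.43 with no filter and -0.39 with the first technical library alone. The abscisic acid call (-0.24, 0.0469; 0.660 as the adjusted p with an estimated correlation) was lost without treated wild-type replicates 2 (0.0577) or 3 (0.0923) or treated memory-line replicate 1 (0.168). The 12 lists not called were the root marker (-0.01, 0.579), iron deficiency (-0.29, 0.432), DNA damage (0.10, 0.0873), mitosis (-0.06, 0.432), DNA replication (-0.09, 0.426), silenced loci (-0.10, 0.662), methylation machinery (-0.07, 0.211), flowering (0.06 with a mean of -0.02, 0.459), early wound (-0.07, 0.389), ethylene (-0.16, 0.193), mitochondrial stress (0.08, 0.238) and flavonoid lists (0.04, 0.337).

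The difference between the genotypes was compared with and without the drug, 2 comparisons that share no library. Of the 258 genes called without azacytidine, 214 (83.0%) had the same sign with it. AT3G04650, UPOX, G6PD4 and AT1G30170 rose in both, 4 genes against 0.0347 expected for independent lists, and no gene fell in both in edgeR. The median size of the log2 change of the 258 genes was 0.321 times as large on azacytidine as without it. Such a ratio is lowered by the choice of genes in the first comparison. Across all genes r was 0.314 and rho 0.234. The share of same-sign genes was 72.3% without treated memory-line replicate 2 and 88.6% without treated memory-line replicate 1.

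The memory line without drug and wild type on azacytidine were also displaced from untreated wild type in like directions. Of the 258 genes called in the memory line, 217 (84.1%) had the same sign on azacytidine in wild type; 68 rose in both, 34 fell in both, and 4 were called in opposite directions (AT3G46270, AT5G02940, WR3 and NAS2, named after their values were seen). Both comparisons use the same 3 untreated wild-type replicates, which alone makes signs agree. Over 16794 genes, 69.9% had the same sign and r was 0.41, while 50 simulations with the same controls, independent genes and no effects gave means of 64.7% and 0.448. The covariance was 0.0711 observed and 0.0233 simulated, a difference of 0.0478. With different wild-type replicates as controls for each comparison, the covariance ran from 0.0225 to 0.072 and r from 0.122 to 0.364 over 6 splits.

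The last comparison asked which genes responded to azacytidine differently in both genotypes. The 4 genes called were all lower in the untreated memory line than in any other group, and their treated level was close to that of treated wild type. For scpl31 the levels were 44.2 ± 5.69 CPM in wild type and 24.2 ± 1.56 in treated wild type (SD, n = 3 each), 9.51 ± 1.57 in the memory line and 26.53 ± 3.37 in the treated memory line (SD, n = 2 each). The other 3 were chosen after their values were seen: AT1G52120, at 0.701 ± 0.327 CPM in the memory line and 6.95 ± 1.47 on azacytidine, AT1G74770, at 13.7 ± 0.65 and 34.5 ± 1.01 CPM, and AT3G62040, at 27.4 ± 3.88 and 84.3 ± 29.4 CPM.

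In edgeR 4 genes differed, while DESeq2 called 93 and 1891 genes had an unadjusted p under 0.05. The difference of the responses was 2.36 for scpl31 (SE 0.22, adjusted p = 0.00154), 3.22 for AT1G52120 (SE 0.44), 1.44 for AT1G74770 (SE 0.19) and 1.86 for AT3G62040 (SE 0.26), the last 3 with an adjusted p of 0.0321. The changes on azacytidine in wild type and in the memory line were -0.87 and 1.49 for scpl31, 0.03 and 3.24 for AT1G52120, -0.11 and 1.33 for AT1G74770, and -0.24 and 1.62 for AT3G62040; in wild type only that of scpl31 was called. The count was 1 without wild-type replicates 1 or 2, treated wild-type replicate 2 or treated memory-line replicate 1, and 2 without treated wild-type replicate 3. It was 7 and 8 without memory-line replicates 1 and 2, 11 without treated memory-line replicate 2 and 48 without wild-type replicate 3. Only scpl31 kept its call in all alternatives that were run.

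No list member differed between the responses over all genes, and 9 lists were called. Iron deficiency genes had a difference with a median of 0.85 (adjusted p = 0.000167; adjusted p = 0.562 with an estimated correlation), and 5 of 15 were called upward adjusted over the list alone. Evening clock genes had a median of -0.49 (adjusted p = 0.000344; adjusted p = 0.495 with an estimated correlation), with 3 of 11 down adjusted over the list alone. The iron median was 0.38 without wild-type replicate 2, 1.28 without treated wild-type replicate 1 and 0.50 without treated memory-line replicate 1, and the evening clock median -0.30 without memory-line replicate 2. The early wound list (0.77, 0.000519; 0.644 as the adjusted p with an estimated correlation) lost its call without treated memory-line replicate 1 (0.0611), with medians of 1.19 and 1.202 without memory-line replicate 2 and treated replicate 2, and the heat shock list (0.56, 0.00926; 0.495 as the adjusted p with an estimated correlation) without memory-line replicate 2 (0.121), with medians of 0.92 without memory-line replicate 1 and 0.37 without treated replicate 2. The phosphate list (-0.55, 0.00282; 0.562 as the adjusted p with an estimated correlation) lost it without memory-line replicate 1 (0.177, median -0.32) or treated replicate 2 (0.134, median -0.27). Its median was -1.49 without treated memory-line replicate 1, -1.18 without memory-line replicate 2, -0.98 without wild-type replicate 1, and -1.16 with the stricter filter or the first technical library alone. The cold list (-0.97, 0.00316; 0.495 as the adjusted p with an estimated correlation) lost it without memory-line replicate 2 (0.143, median -0.22) or treated replicate 2 (0.141). The photosynthesis list (-0.36, 0.00349; 0.792 as the adjusted p with an estimated correlation) turned to medians of 0.22 and 0.06 without these 2 replicates and had medians of -0.81 and -1.09 without replicates 1 of these groups.

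The abscisic acid list (median -0.37, adjusted p = 0.0210; adjusted p = 0.620 with an estimated correlation) lost its call without wild-type replicate 3 (0.0789), memory-line replicate 2 (0.546, median -0.007) or treated memory-line replicate 1 (0.0542), and had a median of -0.63 without memory-line replicate 1. The methylation machinery list (-0.21, 0.0355; 0.792 as the adjusted p with an estimated correlation) lost it without wild-type replicates 1 (0.198) or 2 (0.0703), treated wild-type replicate 2 (0.222, median -0.13), memory-line replicate 1 (0.695, median -0.06), treated memory-line replicate 1 (0.544, median -0.08) or the filter on low counts (0.0557); the median was -0.335 without wild-type replicate 3 and -0.34 without treated memory-line replicate 2. Adjusted over the list alone, 2 phosphate genes and 3 abscisic acid genes were down, and 1 abscisic acid gene and 1 heat shock gene were up. No member gene of the early wound, cold, photosynthesis or methylation machinery lists was called by that adjustment. The lists not called were the jasmonate (-0.14, 0.331), glucosinolate (0.16, 0.986), root marker (0.20, 0.0528), morning clock (-0.72, 0.0549), auxin (-0.23, 0.0967), mitochondrial stress (0.34, 0.110), mitosis (-0.13, 0.132), ethylene (0.28, 0.177), DNA replication (-0.20, 0.180), DNA damage (-0.21, 0.348), flavonoid (-0.09, 0.646), flowering (-0.03, 0.808), salicylate (0.15 with a mean of -0.40, 0.743) and silenced loci lists (-0.19 with an upward statistic, 0.857). Of these, adjusted over the list alone, 1 morning clock, 1 mitochondrial stress and 2 root marker genes were up and 2 morning clock genes down.

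Of the 15 genes named in every comparison, SDC alone was called, and only in both azacytidine responses. LHY, FLC, FT and AOX1A were called in no comparison: AOX1A, the alternative oxidase gene, was at 37.7 ± 8.47 CPM in wild type and 34.4 ± 5.32 in the memory line, and FT, a flowering signal, at 1.35 ± 0.58 and 3.26 ± 1.77 CPM (adjusted p = 0.223). FLC, with 68.1% of its exon bases under antisense exons, was at 2.04 ± 0.33 and 2.97 ± 1.25 CPM. Of the seed storage genes 3 were tested, CRA1, OLEO4 and EM6, and none was called in any comparison by edgeR; the largest difference was that of CRA1 in memory line against wild type, at 7.09 (SE 1.52, adjusted p = 0.0720).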

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

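Of the tests below, that on silent loci in wild-type replicate 3 was chosen before its result was seen; that on memory-line RNA and that on strands were chosen after.

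A test of the difference between both azacytidine responses, and so a difference between groups, singled out 4 genes, with differences in log2 fold change of 2.355 for scpl31, 3.216 for AT1G52120, 1.444 for AT1G74770 and 1.861 for AT3G62040. The same test on gene lists singled out those with median differences of -0.487 (evening clock), -0.212 (methylation machinery), -0.367 (abscisic acid), -0.969 (cold regulon), 0.772 (early wounding), 0.563 (heat shock), -0.361 (photosynthesis), 0.851 (iron deficiency) and -0.547 (phosphate starvation); with an estimated correlation no list passed. Of all reads of memory-line replicate 2, 25.7% aligned to more than 1 place, and such reads were not used in the comparisons.

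Wild-type replicate 3 lay between the other untreated wild-type replicates and the treated and memory-line plants. RNA of treated wild type mixed into it could displace it so, but 91 loci silent in the other untreated replicates stood in it at 1.69% of their treated level, while other genes were displaced by a median of 55.45%, which argues against that mixing. RNA of the memory line could do so too, but of 108 genes that differed at least 4-fold, 12 lay over 3 SD from the level of a mix of 54.6%, which argues against it as well. AT3G04650, chosen after its values were seen, was at 8.75 CPM in replicate 3, where such a mix would hold 32.1. No biological explanation was tested, since the labels give replicate 3 no group of its own.

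In each library 48.2% to 49.3% of the uniquely aligned reads lay in no gene, and antisense genes inside exons of abundant genes had high counts. Counting by a single strand, although the kit does not mark the strand, might give both. Over 104 pairs of an antisense gene and the coding gene around it, the median ratio of counts per kb was 0.78, with quartiles of 0.291 and 1.59, and 48 pairs lay between 0.5 and 2. The median lies where such counting would put it. High antisense counts had prompted the test, however, so the ratio measures the same observation again. Reads that fitted more than 1 gene have their own summary value, 0.263% to 0.778% of the uniquely aligned reads of each library. Were strand ignored, reads inside both genes of a pair would stand there, not in the count of the antisense gene. The median ratio of 0.78 therefore argues against counting without strand for these pairs. The sources name no counting program to check this against. No biological explanation was tested.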

How the results depend on the processing

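MSH1 had no call in 4 of 5 comparisons under all alternatives; in the wild-type response it was called by voom (0.532) and with the 26 libraries as independent samples (0.501), and ranged from 0.275 to 0.776 with a replicate left out. Of genes named by the rule and called, 2 of 21 kept the call throughout in memory line against wild type, 18 of 52 in the wild-type response, 7 of 24 in the memory-line response, 1 of 1 in the difference of responses and 0 of 5 between treated plants; none reversed. Size factors, ranks and genes under antisense exons left out moved no count of calls past 1.5 times. Leaving out organelle genes removed no tested gene, so it tests nothing. In simulated counts of this design edgeR recovered 44% to 57% of 2-fold and 81% to 92% of 4-fold changes between pairs of groups, and 24% and 71% in the difference of responses; depth alone was not tested as a limit. Where a memory-line replicate is left out, the lone sample is assumed to vary like the other groups. The cause was not tested for any change below, and with a replicate left out counts of calls rose as well as fell.

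Genes called in memory line against wild type numbered 904 with DESeq2, 39 with only its groups, 1594 with voom, 4135 with 26 independent libraries and 32 to 891 with a replicate left out. In the wild-type response they numbered 3571 with voom, 6582 with independent libraries and 432 to 2500; in the memory-line response 384 with DESeq2, 95 with only its groups, 618 with voom, 2147 with independent libraries and 91 to 283. In the difference of responses they numbered 7 with no filter, 93 with DESeq2, 384 with voom, 1967 with independent libraries and 1 to 48. Between treated plants they numbered 29 with no filter, 3 with the stricter filter, 282 with DESeq2, 203 with only these groups, 2 with the first library, 918 with voom, 3693 with independent libraries and 1 to 22.

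With an estimated correlation 0 lists were called in memory line against wild type, 0 in the wild-type response, 0 in the memory-line response, 0 in the difference and 0 between treated plants. With a replicate left out the lists called ranged from 7 to 12, 10 to 14, 9 to 16, 9 to 12 and 7 to 13 in that order. Of 55 called list medians, 37 moved by over 1.5 times with a replicate left out and 9 in other alternatives; 10 of the 37 kept the call in all alternatives but the estimated correlation. With a replicate left out, medians of lists whose median or statistic turned ran from 0.005 (without memory-line replicate 1) to 0.391 for DNA damage in memory line against wild type, from -0.098 to 0.806 for iron deficiency in the memory-line response and from -0.083 to 0.602 for salicylate immunity in the wild-type response. For photosynthesis they ran from -0.924 to 0.334 in the memory-line response, from -1.093 to 0.218 in the difference and from -0.935 to 0.193 between treated plants. Without memory-line replicate 2 those of photosynthesis were 0.334 and 0.218, and without treated memory-line replicate 2 they were 0.103, 0.059 and 0.193. Same-sign shares of both azacytidine responses were 78.85% with DESeq2, 74.12% with voom, 70.3% with independent libraries and 70.57% to 90.08% with a replicate left out. Those of the memory-line difference with and without azacytidine were 69.23% with only its groups, 75.22% with voom, 72.48% with independent libraries and 72.3% to 88.6%.

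With the replicate number as a block, 685 genes were called in memory line against wild type, 1323 in the wild-type response, 179 in the memory-line response, 11 in the difference and 123 between treated plants, and the memory-line same-sign share was 89.34%. Between treated plants the block moved the median of morning clock genes from -0.59 to -0.372 and that of cold genes from -0.295 to -0.541. Deviations of wild-type and treated wild-type replicates with the same number correlated at 0.20, 0.01 and 0.05, and not every replicate correlated best with its own number. Replicates 1 and 2 correlated at 0.27 and 0.24 between the treated genotypes and at 0 and 0.26 between the untreated genotypes. They correlated at 0.17 and -0.03 between wild type and the treated memory line, and at -0.04 and 0.07 between treated wild type and the memory line. Between the untreated and treated memory line both correlated at -0.26. That is a single observation, since the deviations of 2 replicates from their mean mirror each other. The samples share only a number.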

Other observations

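Of the tests below, those on gene density, pentatricopeptide repeat genes and the displacement of wild-type replicate 3 were chosen after the result was seen; those on shared controls and on regrouped replicates were chosen before, except for the simulated splits of the controls, chosen after.

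The 78 genes that rose on azacytidine in both genotypes lay in gene-poor parts of the chromosomes. They had a median of 78 coding genes within 250 kb, against 136 for all tested genes, and 10000 random sets of tested genes gave medians of 128 to 143.5. The random sets were not matched for level without the drug, and 48 of the 78 had at most 3 counts in every untreated replicate. The gap therefore does not set these genes apart from silent genes in general. Some of the 78 also overlap each other, as AT2G03965 and AT2G04655 do, and share a neighbourhood. Of the 78, 76.9% lay below the first quartile of all tested genes. In the treated memory line 23 of them were higher than in treated wild type, with a median log2 ratio of -0.30.

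Among the 153 genes that rose in the untreated memory line 5 encode pentatricopeptide repeat proteins, a family that mostly acts on RNA in plastids and mitochondria: MEE40, SVR7, AT5G10690, AT5G46580 and AT5G47460, named after their values were seen. By chance 1.66 were expected (Fisher p = 0.0259, adjusted p = 0.104). Of 239 tested genes of the family 218 were higher in the memory line, with a median of 0.44 (camera p = 4.15e-21; p = 0.0718 with an estimated correlation). In treated wild type 214 were higher, with a median of 0.36 (camera p = 6.19e-13; p = 0.147 with an estimated correlation), and 11 rose, against 7.21 expected, which did not pass the test (Fisher p = 0.177, adjusted p = 0.271). Both comparisons use the same 3 untreated wild-type replicates, so low values in these would raise the family in both.

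Genes changed in the untreated memory line were displaced the same way in treated wild type. The 3 untreated wild-type replicates that both comparisons share could produce this, but with different replicates as controls the covariance would then be about 0, and its lowest and mean values over 6 splits were 0.0225 and 0.0478. Simulated splits with no effects gave lowest values of -0.00417 to 0.00171 (central 95%) with independent genes, but with the correlation between genes kept as among the replicates 6.1% of 1000 simulated lowest values and 4.5% of the mean values were at least as high as those observed, which leaves the question open. Variation among untreated wild-type plants along the same direction may contribute. Wild-type replicate 3 was itself displaced by 43.2% of the azacytidine change, against 62% and 43.1% in memory-line replicates 1 and 2. Wild-type replicates 1 and 2 are the start of both the displacement and the azacytidine change, so their own spread raises these shares. No share without effects was computed, so they do not show how much such variation contributes. A response of the memory line that resembles that to azacytidine remains as a biological explanation and was not separated from the shared controls or from this variation.

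The 6 wild-type replicates can be split into 2 groups of 3 in 10 ways. Only 1 split, that by treatment, gave 1408 calls and the highest other gave 0. The 10 splits are too few to decide.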
